A study of Mus musculus with 6 samples.

How the data were processed

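Small RNA libraries were made from bone marrow cells of mice. The series' design text names lineage-negative (Lin-) cells, the fraction of bone marrow depleted of mature blood cells and enriched for stem and progenitor cells, and 2 genotypes: wild type and a maternal knockout (KO), here taken as inheritance of the mutation from the mother. The part of the locus that was deleted is not given in the sources used here. There were 3 KO and 3 wild-type (WT) libraries, and the group and replicate number of each were taken from its title. Nothing in the labels says whether the 3 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

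Per the labels' protocols, total RNA was extracted with Trizol, a small RNA kit from NEB was used for adapter ligation and first strand synthesis, and PCR products of the size of snoRNAs plus adapters were cut from a gel and sequenced on a NovaSeq. This size selection sets which RNAs can be seen: mature miRNAs are shorter than the selected inserts, so reads assigned to a miRNA feature are described here as reads of the precursor's region. Per the submitters' processing notes, Trimmomatic 0.38 and Bowtie2 2.3.4.1 were used with the mouse genome build GRCm38. The counting tool, the annotation, the treatment of reads with several matches and the strand setting are not given in the sources used here.

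The deposited values are read counts per non-coding RNA feature, 1 table per library, and the authors list only features with at least 1 read, so a feature missing from a library was set to 0. No normalization of the deposited counts is recorded. Features are named by position. Of 1823 features listed in at least 1 library, 1822 matched a gene of GENCODE release M21 on GRCm38 at the same start and end, and the last is the accession of the 45S pre-rRNA, the precursor of the ribosomal RNAs. A symbol shared by several features was found for 36 features, which were kept apart by position. Many snoRNAs carry only a provisional symbol starting with Gm, so lists defined by name are partial. A second symbol was taken from RefSeq on the same build for 1129 features, where both overlapped by at least 80%. Identical sequences or features overlapping by at least 80% on either strand formed 77 groups with 294 features, the largest of 43 features. The counts of single members of such groups are uncertain because reads could have been split among them, and without a stated strand setting, reads of overlapping antisense features cannot be told apart.

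Total counts were 48476416, 51837721 and 47299957 in KO replicates 1 to 3 and 53299322, 45398303 and 50775854 in WT replicates 1 to 3. A few snoRNAs took most of the reads: the most abundant feature had 16.9% to 19.9% of the counts of a library and the 10 most abundant had 63.0% to 65.7%. Levels are given as CPM, the count scaled by the library's total. Intervals and floors (95%, exact Poisson or exact binomial) cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Over features with at least 20 counts in a pair of replicates, the chi-square statistic per degree of freedom was 530 to 3308 in the 6 pairs, so no 2 replicates differed by as little as sampling noise.

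The deposited counts were tested with edgeR 4.0.16 (quasi-likelihood test, package defaults, R 4.3.3): TMM normalization, the default expression filter (minimum count 10, minimum total count 15), KO against WT with no other term, two-sided, Benjamini-Hochberg adjustment over all features tested, threshold 0.05. The filter left 624 features. Log2 fold changes are KO over WT. Their standard errors (SE) were taken as the size of the log2 fold change divided by the square root of the F statistic and are approximate. Gene lists were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry from limma 3.58.1 on log2 CPM (prior count 2) where at least 5 members passed the filter, adjusted over the 7 lists so tested (10 without the filter). Camera compares a list with the other tested features, so a list it calls higher or lower is so relative to them. Its calls of different lists are therefore not separate findings. Single values per library were compared with exact two-sided permutation tests, and an exact test of 3 libraries against 3 cannot go below p = 0.1. In a self-test on counts simulated for the 624 features with 200 changed, edgeR recovered 24.0% of the features changed 2-fold, 93.4% of those changed 4-fold and 100% of those changed 32-fold, and DESeq2 recovered 43.9%, 96.9% and 100%.

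The tests, the alternatives, the lists and the rule for named features were fixed before the data were examined, unless stated otherwise. The lists were the snoRNAs, miRNAs and long transcripts of the Dlk1-Gtl2 locus (by name or by position between Dlk1 and Dio3), snoRNAs of the Snurf-Snrpn imprinted cluster, C/D box snoRNAs (names starting Snord), H/ACA box snoRNAs (Snora), small Cajal body RNAs, snoRNAs hosted by Gas5, Rpl13a and Snhg1, RNAs of pre-rRNA cleavage, spliceosomal snRNAs, other polymerase III RNAs, mitochondrial RNAs, and markers of erythroid, mature myeloid, B lymphoid, T lymphoid, megakaryocyte, primitive haematopoietic and stromal or endothelial cells. No locus long transcript and no megakaryocyte marker was among the listed features. Named features are the up to 12 tested locus snoRNAs with the highest mean CPM, outside the locus up to 8 called features with the largest fall and 8 with the largest rise whose groups did not overlap, the 2 tested members with the highest mean CPM of each other list, the 4 features with the highest mean CPM, and up to 4 locus miRNAs or long transcripts that passed the test. Any other feature named was chosen after its values were seen.

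Alternatives covered other size factors (RLE, library size alone, TMM without the locus), no filter, a filter of at least 50 counts in 3 libraries, robust fitting, DESeq2 1.42.0, a block for the replicate number, leaving out each library, list membership, and other denominators for shares. 5 kinds of alternatives were added after the data were seen: edgeR's newer quasi-likelihood method, removal of a length trend per library (loess, span 0.5), summing of identical or overlapping copies, leaving out KO replicate 2 with 1 WT library, and summing the locus snoRNAs to 1 feature. The choice between edgeR's default and its newer method had not been fixed in advance. Exploratory fits used the default, a first version of the full analysis used the newer method, and the default was made the main test after the results of both had been seen. The adjusted p of the 1 called feature was 0.0242 with the default and 6.2e-04 with the newer method, and both called that feature alone. No library was left out of the main tests. Python 3.11.15, pandas 2.3.3, SciPy 1.17.1, edlib 1.3.9.post1 and matplotlib 3.10.9 were used for joins, resampling, sequence comparison and figures.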

Results

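Reads of small non-coding RNAs were counted in lineage-negative bone marrow cells of wild-type mice and of mice with a maternal KO at the Dlk1-Gtl2 locus, an imprinted region of chromosome 12 whose non-coding RNAs are expressed from the maternal chromosome. Small nucleolar RNAs (snoRNAs) guide chemical modification of ribosomal and other RNAs. The series asks which small RNAs change when the maternal copy is mutated, with the snoRNAs of this locus and ribosomal RNA modification as its subject. There were 3 libraries per genotype, with 45398303 to 53299322 counts each, and 1176 to 1308 features with at least 1 read in a library.

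The snoRNAs of the locus were nearly absent from the KO libraries. GENCODE places 23 snoRNAs between Dlk1 and Dio3 (chromosome 12, 109463336 to 110279068, GRCm38), and 10 of them had a read in any library. All 10 had more reads in the WT than in the KO libraries, and 7 had no read in any KO library. DQ267100, DQ267102 and Gm26922 held 162, 50 and 43 of the 287 WT reads. Gm26922 is among the 7, and the others of the 7 had at most 8 WT reads each, so their zeros carry little weight singly. Together the 10 had 3, 2 and 2 reads in KO replicates 1 to 3 and 87, 106 and 94 reads in WT replicates 1 to 3. The summed level was 0.0476 ± 0.0125 CPM in the KO and 1.94 ± 0.36 CPM in the WT libraries (SD, n = 3 each), and the exact permutation test gave p = 0.1, the smallest this design allows. The pooled level was 40.5-fold lower in the KO libraries, with a counting interval of 19.4 to 102. The locus snoRNAs were rare even in the WT libraries.

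DQ267100 was the 1 locus snoRNA abundant enough for the main test, and it fell. It is a 72-nt C/D box snoRNA on the plus strand of chromosome 12, 109649617 to 109649688, within an exon of Rian, a maternally expressed long non-coding RNA that hosts snoRNAs. Its sequence is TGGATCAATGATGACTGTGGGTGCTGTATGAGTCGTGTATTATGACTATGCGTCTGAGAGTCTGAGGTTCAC. It had 2, 0 and 1 reads in the KO and 59, 51 and 52 reads in the WT libraries. Its level was 0.0208 ± 0.0206 CPM against 1.08 ± 0.05 CPM (SD, n = 3 each), a pooled fold of 53.3 with a counting interval of 17.9 to 261. The fitted log2 fold change was -5.50 (SE 0.58), with an adjusted p of 0.0242 by edgeR's quasi-likelihood test. The log2 fold change stayed between -6.31 and -4.89 with any 1 library left out. The adjusted p was 0.0311 without KO replicate 1 and 0.0266 without KO replicate 2, but 0.400 without KO replicate 3, 0.188 without WT replicate 1, 0.197 without WT replicate 2 and 0.215 without WT replicate 3. With the replicate numbers as a block it was 0.344.

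A pair of related snoRNAs of the same host, named after their values were seen, was also low in the KO libraries. Gm26922 (AF357355 in RefSeq, chromosome 12, 109654627 to 109654698, in an exon of Rian) had 0, 0 and 0 reads in the KO and 6, 20 and 17 in the WT libraries. Against a floor of 3 counts over the KO group it was at least 14.2-fold lower. That floor leaves out the counting error of the WT reads, and the counting interval that includes it starts at 11.02-fold. DQ267102 (109656345 to 109656416, in an intron of Rian) had 1 read in each KO library and 12, 28 and 10 in the WT libraries, a 16.5-fold difference with a counting interval of 5.32 to 82.5. DQ267102 is the annotated locus snoRNA closest in sequence to DQ267100, at 15 edits over 72 nt (79.2% identity). Neither passed the expression filter. With no filter edgeR's quasi-likelihood test called 3 locus snoRNAs, with adjusted p of 7.6e-06 for DQ267100, 0.00103 for Gm26922 and 0.00557 for DQ267102. As a set without the filter, the 10 locus snoRNAs were lower in the KO libraries by camera (adjusted p = 5.3e-09 over the 10 lists tested without the filter), by camera with an estimated correlation (adjusted p = 0.0460) and by fry (adjusted p = 0.00269). Summed to 1 feature, an alternative chosen after the data were seen, they had a log2 fold change of -5.21 (SE 0.38) with an adjusted p of 0.00206 by edgeR and of 4.1e-13 by DESeq2.

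**Figure D1:**
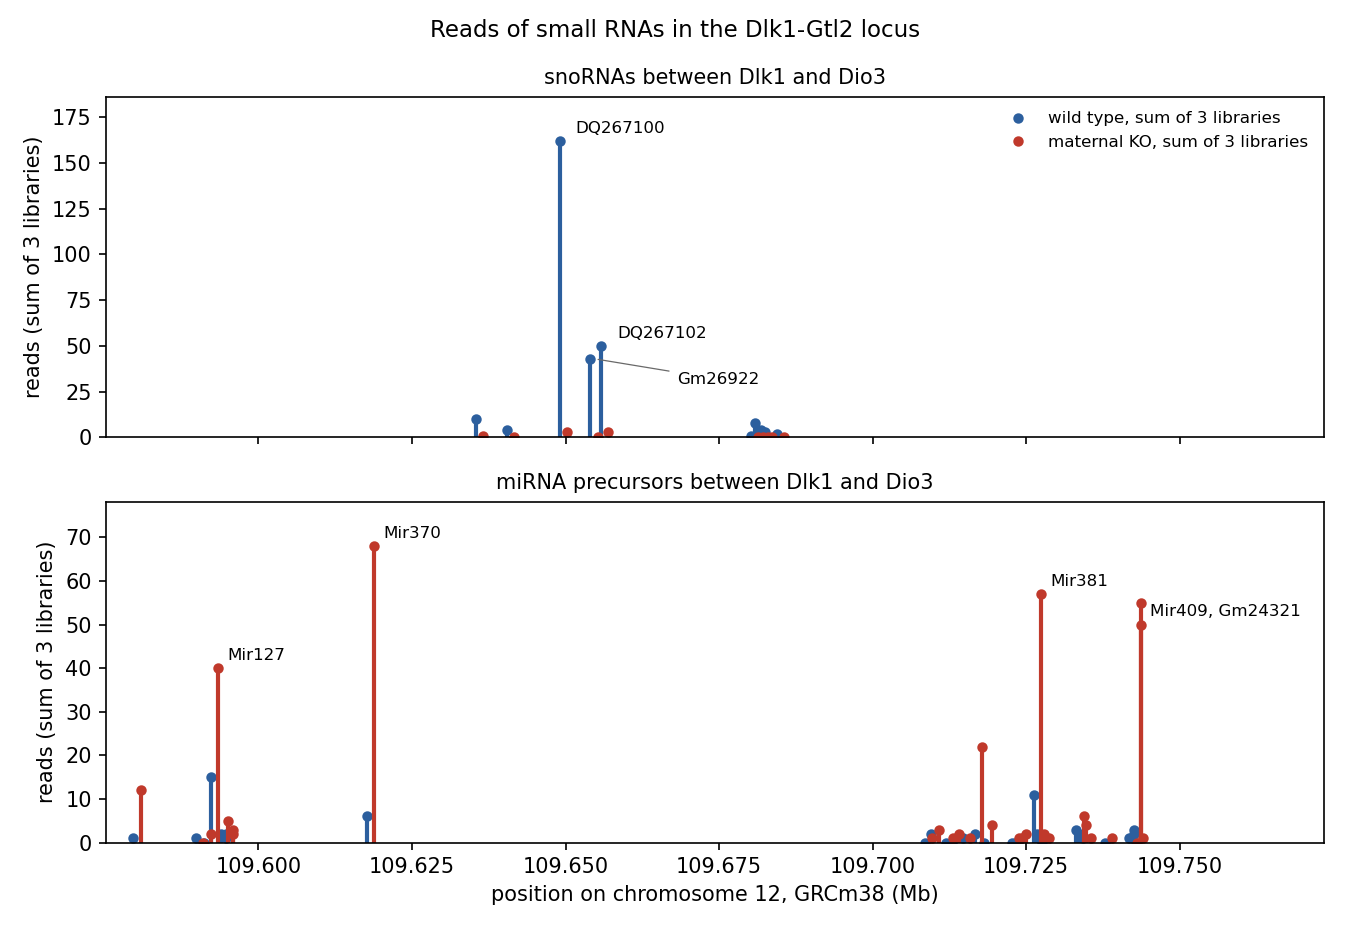
Reads of each listed snoRNA (top) and miRNA feature (bottom) of the locus, summed over 3 libraries per genotype, against position on chromosome 12 (GRCm38, Mb); each stem is 1 feature, and the genotypes are drawn slightly apart for legibility. DQ267100 had 162 reads in the WT and 3 in the KO libraries, while Mir370 had 6 and 68.

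The miRNA features of the locus did not show the fall seen in its snoRNAs. Of 29 listed, 24 had more reads in the KO libraries, 2 had more in the WT libraries and 3 had as many in both. Many of the 24 differed by only 1 or 2 reads, such as Mir411 with 3 in the KO and 2 in the WT libraries, so the count does not show a rise of each. The sum of the 29 was 19, 109 and 220 reads in KO replicates 1 to 3 and 2, 36 and 20 in WT replicates 1 to 3, or 2.38 ± 2.14 CPM against 0.408 ± 0.378 CPM (SD, n = 3 each). The groups overlapped, since KO replicate 1 and WT replicate 3 had 0.392 and 0.394 CPM, and the exact permutation test gave p = 0.3. The log2 ratio of the group means was 2.55, and it was 1.61 without KO replicate 3 and 3.46 without WT replicate 2. None of the 29 passed the filter, so none is named by the fixed rule. The highest sums, chosen after their values were seen, were those of Mir370 with 68 reads in the KO and 6 in the WT libraries, Mir381 with 57 and 11, Gm24321 with 55 and 2, Mir409 with 50 and 3, and Mir127 with 40 and 15. Gm24321 lies antisense to Mir409 at the same place, and their reads cannot be told apart. With no filter edgeR's quasi-likelihood test called 3 of the 29, all higher in the KO libraries: Mir370 (adjusted p = 0.0299), Mir409 (0.00966) and Gm24321 (0.0136). Their reads in KO replicates 1 to 3 and WT replicates 1 to 3 were 4, 9, 55 and 0, 5, 1 for Mir370, 3, 12, 35 and 0, 1, 2 for Mir409, and 0, 15, 40 and 0, 0, 2 for Gm24321. As a set without the filter, the locus miRNAs were higher by camera (adjusted p = 8.9e-07 over the same 10 lists), and this was lost with an estimated correlation (adjusted p = 0.464) and with fry (adjusted p = 0.417).

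**Figure D2:**
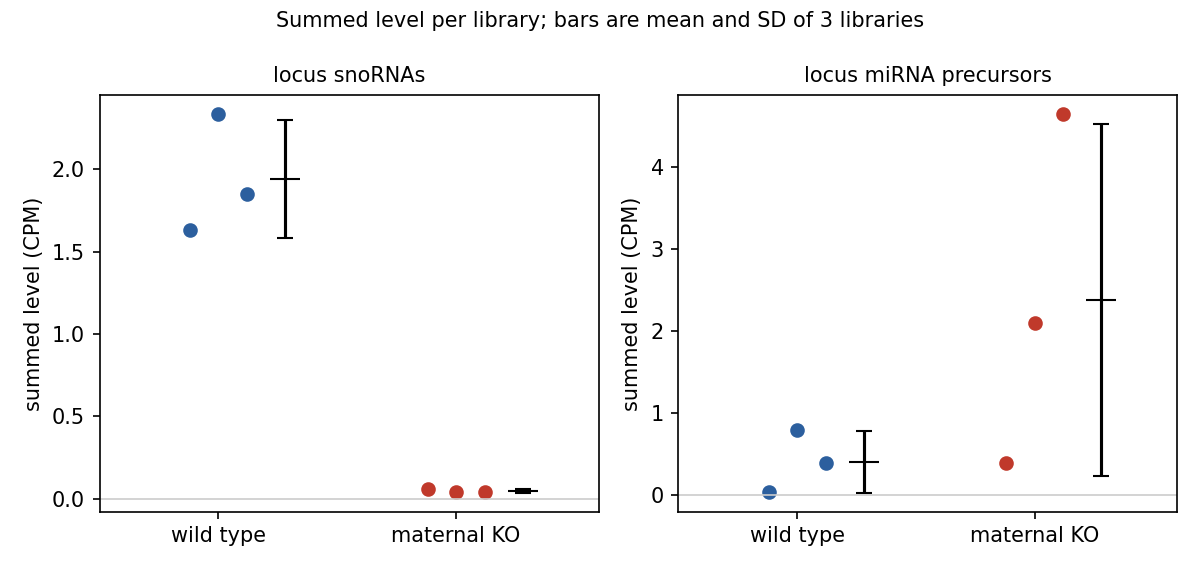
Summed level in CPM of the 10 locus snoRNAs (left) and the 29 locus miRNA features (right) in each library (points), with the mean and SD of 3 libraries per genotype (bars). The snoRNA sums of the genotypes do not overlap, while the miRNA sum of KO replicate 1 lies among the WT values.

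Outside the locus no feature was called. Among 624 features tested by edgeR's quasi-likelihood test, 1 had an adjusted p under 0.05, which was DQ267100, and DESeq2 called the same 1. At an unadjusted p under 0.05 there were 40 features, 27 lower and 13 higher in the KO libraries. The genotypes did not overlap for 95 features (15.2%, where chance gives 10%). The self-test recovered 24.0% of 2-fold changes, so changes of that size could be missed, while it recovered 93.4% of 4-fold changes. It had 200 of the 624 features changed, which eases the adjustment. It therefore does not show how often a 4-fold change would be called where few features change. The median log2 fold change of all tested features was -0.08 with TMM, 0.02 with RLE size factors and -0.16 with library size alone, and the values of lists are to be read against it.

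The most abundant snoRNAs differed little between the genotypes. Gm26224, in an exon of the snoRNA host gene Gas5 (chromosome 1, 161035394 to 161035473), had 196097 ± 2868 CPM in the KO and 174030 ± 5395 CPM in the WT libraries, a log2 fold change of 0.24 (SE 0.06) that was not called (adjusted p = 0.542 by edgeR). Gm25789, also in Gas5, had 81305 and 80939 CPM. Snord49a had 91380 and 93726 CPM, and Snord68, hosted by Rpl13, had 66947 and 68367 CPM, and each of these 3 differences was smaller than the SD of either genotype. Among lists of hosts by name, none of the 4 Gas5-hosted, 4 Rpl13a-hosted or 1 Snhg1-hosted snoRNAs was called, over all features or adjusted over the list alone. By position, a list added after the data were seen, Gas5 holds 10 tested snoRNAs, of which 8 had higher estimates in the KO libraries. None of them was called by edgeR over all features and 1, Gm26224, was called adjusted over the list alone (adjusted p = 0.0388). Snord47 of Gas5 had 7569 ± 109 and 7849 ± 290 CPM, the feature named Snord80 with the most reads 14183 ± 3418 and 14188 ± 2233 CPM, Snord34 of Rpl13a 2057 ± 193 and 2027 ± 217 CPM, Snord32a 960.4 ± 43.1 and 1039 ± 114.8 CPM, and Snord22 of Snhg1 16.1 ± 6.4 and 21.8 ± 5.5 CPM (KO and WT, mean and SD, n = 3 each).

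The paternally expressed snoRNAs of the Snurf-Snrpn cluster, another imprinted region, served as a comparison. Only 1 of 10 listed members was tested. Snord64 had 0.388 ± 0.111 CPM in the KO and 0.426 ± 0.048 CPM in the WT libraries (log2 fold change -0.08, SE 0.29, adjusted p = 0.947 by edgeR). Of the 82 C/D box snoRNAs listed by name outside both clusters, none was called by the main test, 42 were lower and 40 higher, and camera gave no call (adjusted p = 0.138). With no filter edgeR called 1 member, Snord15a, lower in the KO libraries, with 1428, 1654 and 2231 reads in KO replicates 1 to 3 and 14479, 2723 and 4449 in WT replicates 1 to 3 (log2 fold change -1.89, SE 0.57 in the main test, where it was not called). Camera called the list higher with RLE size factors (adjusted p = 0.0370), with no filter (0.0453), and without KO replicate 3 (0.0383), WT replicate 1 (0.0051) or WT replicate 3 (0.0287), and in none of these with an estimated correlation. A wider C/D list chosen by sequence and length after the data were seen, with 146 tested members, was also called higher by camera (adjusted p = 0.0021, and 0.360 with an estimated correlation). Of its members 67 were lower and 79 higher, with a median log2 fold change of 0.02, so this call is relative to the other features. The median log2 fold change of the 82 snoRNAs listed by name was close to 0, and its sign depended on the scaling.

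H/ACA box snoRNAs, which guide pseudouridylation, were lower as a list. Of 39 tested members 36 were lower in the KO libraries and none was called, over all features or adjusted over the list alone. Their median log2 fold change was -0.29. Camera called the list lower (adjusted p = 0.00264), but the call was lost with an estimated correlation (adjusted p = 0.435) and fry made none (adjusted p = 0.163). It was also lost without KO replicate 2 (adjusted p = 0.0746), and among members with a mean of at least 50 counts (0.0632). In settings added after the data were seen, it was lost without KO replicate 2 and either WT replicate 1 (0.292) or WT replicate 3 (0.0887), and kept without KO replicate 2 and WT replicate 2 (0.0140, and 0.505 with an estimated correlation). A wider H/ACA list chosen by sequence and length after the data were seen, with 92 of 106 tested members lower, was called lower by camera (adjusted p = 3.6e-06, and 0.360 with an estimated correlation), and this rule also takes in Snord15a. The members with the highest mean level varied within genotypes: Snora68 had 177 ± 106 CPM in the KO and 258 ± 166 CPM in the WT libraries, and Snora61 had 99.6 ± 86.3 and 119 ± 57 CPM. KO replicate 2 stood apart by RNA length. Relative to the mean of the 6 libraries its median log2 level was -0.74 for features of 166 to 350 nt and 0.13 for those of 76 to 90 nt, while KO replicate 1 had 0.31 and -0.13.

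**Figure D3:**
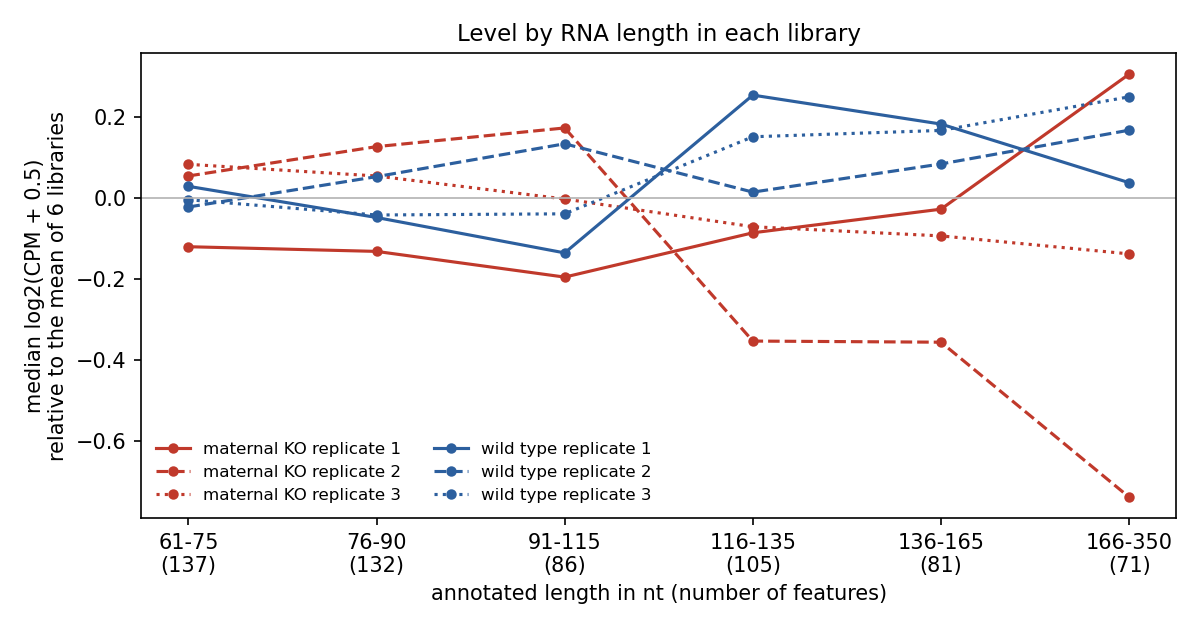
Median log2(CPM + 0.5) of tested features in 6 bins of annotated length (nt, number of features in brackets), for each library relative to the mean of all 6; lines join the bins of 1 library. KO replicate 2 falls to -0.74 in the longest bin, where the WT libraries have 0.04, 0.17 and 0.25.

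Among other housekeeping RNAs no feature was called, and none of their fixed lists was called in the main test. The 21 tested RNAs of pre-rRNA cleavage, among them U3 copies, U8 and Snord14 members, had a camera adjusted p of 0.863. Summing identical or overlapping copies, a setting added after the data were seen, left 12 members and gave 0.808. Snord14d had 702 ± 91 CPM in the KO and 607 ± 36 CPM in the WT libraries (log2 fold change 0.27, SE 0.13), and Snord14c had 481 ± 70 and 402 ± 22 CPM (0.32, SE 0.14), both with an adjusted p of 0.710 by edgeR. All 8 tested spliceosomal snRNAs had lower estimates in the KO libraries, with a camera adjusted p of 0.0553, and of 0.0393 under the filter of at least 50 counts in 3 libraries (0.395 there with an estimated correlation). With the default filter it was 0.270 without KO replicate 2. With identical or overlapping copies summed, a setting added after the data were seen, 5 members were left and camera gave 0.250. Of all 65 tested snRNA features, a list added after the data were seen, 62 had lower estimates, and camera called them lower (adjusted p = 1.4e-06, and 0.360 with an estimated correlation). Some of these features are near-identical copies that could share reads, so neither the count nor the camera call rests on 65 separate RNAs. Rnu1b1 had 105 ± 14 and 120 ± 6 CPM and Rnu1a1 101 ± 12 and 118 ± 7 CPM. These U1 copies are near-identical, and their counts are uncertain. Of 6 other polymerase III RNAs 5 had lower estimates (camera adjusted p = 0.0551). Camera called this list lower under the stricter filter (0.0326), with RLE size factors (0.0406), without KO replicate 3 (0.0383) and without WT replicate 3 (0.0287), in none of these with an estimated correlation, and gave 0.270 without KO replicate 2. The levels were 28.4 ± 3.0 and 36.7 ± 5.3 CPM for Rn7sk, a regulator of transcription elongation, and 18.3 ± 0.8 and 26.2 ± 4.8 CPM for the Y RNA Rny1. The 22 tested mitochondrial RNAs had a camera adjusted p of 0.354, with 176 ± 28 and 197 ± 18 CPM for mt-Rnr2 and 132 ± 7 and 160 ± 16 CPM for mt-Rnr1. The 2 small Cajal body RNAs, Scarna10 (9.49 ± 2.39 and 11.01 ± 0.97 CPM) and Scarna9 (4.80 ± 0.49 and 6.15 ± 0.83 CPM), were not called. Fry called none of the 7 lists tested as sets.

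Markers of blood cell types were measured through miRNA features, and none was called over all features. The cell types are those of the fixed lists, and the reads are of the precursors' regions, so the levels do not measure cell content. Among primitive haematopoietic markers 4 of 5 tested members had higher estimates in the KO libraries, and camera called the list higher (adjusted p = 0.0135). The call of the primitive haematopoietic list was lost with an estimated correlation (adjusted p = 0.435) and with fry (adjusted p = 0.573), and without KO replicate 1 (0.0811), KO replicate 2 (0.0658), WT replicate 1 (0.201) or WT replicate 3 (0.0804). In the added settings it was lost without KO replicate 2 and either WT replicate 1 (0.154) or WT replicate 3 (0.0887), and kept without KO replicate 2 and WT replicate 2 (0.0013, and 0.505 with an estimated correlation). miRNA features outside the locus, a list added after the data were seen, also had mostly higher estimates: 133 of 204 tested, with a median log2 fold change of 0.20 against 0.22 for the primitive haematopoietic list. Camera called them higher too (adjusted p = 3.8e-09, and adjusted p = 0.360 with an estimated correlation). Mir126a, a miRNA of haematopoietic stem cells and endothelium, had 10.2 ± 6.3 CPM in the KO and 3.12 ± 2.44 CPM in the WT libraries (log2 fold change 1.75, SE 0.80, adjusted p = 0.710 by edgeR), and Mir10a had 60.1 ± 5.5 and 58.0 ± 24.3 CPM. Mir150, the 1 B lymphoid marker listed, had 5.16 ± 1.06 and 2.06 ± 1.27 CPM (log2 fold change 1.38, SE 0.54). Its adjusted p by edgeR was 0.710 over all features and 0.0378 adjusted over the list alone, which holds 1 member. On the erythroid list Mir144 had 0.397 ± 0.312 and 0.200 ± 0.032 CPM. On the myeloid list Mir223 had 18.2 ± 4.1 and 13.4 ± 5.3 CPM and Mir142 had 2.13 ± 0.18 and 1.47 ± 0.48 CPM. On the T lymphoid list Mir181a-1 had 12.5 ± 7.4 and 9.73 ± 3.11 CPM and Mir181a-2 had 10.4 ± 5.2 and 8.59 ± 2.64 CPM. Mir143 of the stromal or endothelial list had 1.35 ± 0.44 and 1.04 ± 0.54 CPM. These levels are given KO before WT.

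Shares of RNA classes showed where the reads went. snoRNAs with a provisional name took 58.4% ± 0.3 of the counts in the KO and 56.5% ± 0.5 in the WT libraries, and Snord-named snoRNAs outside the locus 37.0% ± 0.6 and 37.7% ± 0.3. The 45S pre-rRNA took 3.61% ± 0.32 and 4.86% ± 0.25 (SD, n = 3 each), lower in every KO library than in every WT library. Its sequence includes those of the mature ribosomal RNAs, so these reads need not come from the precursor. miRNA features took 0.449% ± 0.040 and 0.443% ± 0.128, snRNAs 0.341% ± 0.070 and 0.404% ± 0.021, Snora-named snoRNAs 0.0627% ± 0.0279 and 0.0810% ± 0.0252, mitochondrial rRNA 0.0308% ± 0.0034 and 0.0357% ± 0.0032, mitochondrial tRNA 0.0275% ± 0.0033 and 0.0269% ± 0.0023, miscellaneous RNAs 0.0102% ± 0.0019 and 0.0153% ± 0.0032, and small Cajal body RNAs 0.00143% ± 0.00022 and 0.00172% ± 0.00006. Over the 11 classes, exact permutation tests gave p = 0.1, the smallest possible, for the 45S pre-rRNA, locus snoRNAs, miscellaneous RNAs, snRNAs and snoRNAs with a provisional name, and p = 0.22 after adjustment. The snRNA shares barely separated, with 0.3867% in KO replicate 1 and 0.3872% in WT replicate 2. Their log2 ratio was -0.25, and -0.35 to -0.085 with 1 library left out.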

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

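Settings named below as added were chosen after the data were seen. The count of called features (1, with 1 locus snoRNA) was the same under RLE size factors, library size alone, TMM without the locus, the stricter filter, DESeq2 (2 adjusted p not given), robust fitting, membership by fixed names and, added, the newer quasi-likelihood method, removal of the length trend and summed copies. Each of these called DQ267100. With no filter 13 features were called, 5 lower and 8 higher, of which 3 were locus snoRNAs (lower) and 3 locus miRNA features (Mir370, Mir409 and Gm24321, higher). Leaving out 1 library gave 0 to 1 calls, and leaving out KO replicate 2 with any 1 WT library (added) gave 0. Fewer libraries entered these fits, and the log2 fold change of DQ267100 stayed between -6.31 and -4.89 in all of them. The other 31 of 32 named features were called under none of those of the 20 alternatives that tested them.

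The correlations of same-numbered deviations from the group means were -0.13, 0.40 and -0.36, and KO replicate 1 correlated best with WT replicate 3 (0.59). They gave no sign that the replicate numbers pair the libraries. With 3 libraries per genotype they cannot exclude a shared batch. With the replicate block 0 features and 0 locus snoRNAs were called, and DQ267100 had a log2 fold change of -5.53 with an adjusted p of 0.344 by edgeR. Lists called by camera stayed at 2, and no class share moved by more than its spread.

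The lists called by camera (2) were 4 with RLE size factors, where C/D box snoRNAs (higher, 0.0370) and other polymerase III RNAs (lower, 0.0406, and 0.417 with an estimated correlation) joined, 5 with no filter, 3 with at least 50 counts in 3 libraries (H/ACA at 0.0127, spliceosomal snRNAs at 0.0393 and other polymerase III RNAs at 0.0326, all lower), 0 among members with a mean of at least 50 counts, 0 with an estimated correlation, 0 to 4 with 1 library left out, 2 others without KO replicate 2 and WT replicate 1 (added; C/D box snoRNAs at 0.0086 and mitochondrial RNAs at 0.0111, both higher, each 0.486 with an estimated correlation), the same 2 without KO replicate 2 and WT replicate 2 (added; H/ACA at 0.0140), and 1 without KO replicate 2 and WT replicate 3 (added). In that last setting the pre-rRNA cleavage RNAs, with lower estimates in the main test, were called higher (adjusted p = 0.0433, and 0.594 with an estimated correlation). Leaving out libraries moved that list's adjusted p between 0.0036, lower without KO replicate 1 (0.578 with an estimated correlation), and 0.803. The list counts U3 copies as separate members, with 12 members left once copies are summed, so these calls rest on fewer separate RNAs than listed. The cause was not tested.

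The log2 ratio of the summed locus snoRNAs was -5.35, and -5.58 to -5.19 with 1 library left out. Of 80 alternatives for class shares 73 moved by less than the spread between replicates. The log2 ratio of the miRNA share (0.02) was -0.0018 per snoRNA read outside the locus and -0.14 to 0.28 with 1 library left out, that of mitochondrial tRNA (0.03) was -0.072 to 0.098, and that of provisionally named snoRNAs (0.05) was 0.029 per snoRNA read. The miRNA and mitochondrial tRNA ratios have no stable direction. Depth limits the locus: 9 of its 10 listed snoRNAs failed the filter.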

Other observations

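Apart from the main test, the fits with no filter or with 1 library left out, and the splits of the libraries, the tests in this part were chosen after the results they measure had been seen, at least in large part.

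Among miRNA features that the expression filter left out, some had most of their reads in 1 or 2 libraries, and they were named after their values were seen. Mir1a-1, Mir1a-2, Mir133a-1 and Mir133a-2, best known from skeletal and heart muscle, had 258, 262, 118 and 116 reads in KO replicate 2, and at most 9 in any other library. Mir122, the main miRNA of hepatocytes, had 20 and 23 reads in WT replicates 1 and 2, 1 read in KO replicate 2 and 0 in the other 3 libraries. With no filter, edgeR called these 5 features, so these calls rest mainly on 1 or 2 libraries. Mir100, by contrast, passed the filter and was not called in the main test. It had 14, 335 and 24 reads in KO replicates 1 to 3 and 492, 228 and 220 in the WT replicates. Without KO replicate 2 its log2 fold change was -3.83 (SE 0.53, adjusted p = 0.107 by edgeR's quasi-likelihood test).

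With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The genotype split called 1 feature, and the highest of the other splits called 0, so 1 of the 10 splits called as many. For lists called by camera the genotype split gave 2 and the highest other split 4, and 8 of the 10 splits gave at least 2.

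The reads of locus miRNAs were higher in KO replicates 2 and 3 while the locus snoRNAs were nearly absent. The tables argue against a general difference in the recovery of miRNA features, because other miRNAs did not rise alike. The summed locus miRNAs had a log2 ratio of 2.55, at percentile 100 of 10000 random lists of 29 other miRNAs matched on total count. The central 95% of these lists ran from -0.70 to 0.41. They draw unrelated miRNAs, while the locus miRNAs vary together (estimated correlation 0.46), so the percentile overstates how unusual the sum is. The overlapping pair at Mir409 did not carry all of the pooled difference, since the pooled ratio without both was 4.64 (counting interval 3.44 to 6.37). That interval leaves out the spread between libraries, so it does not show a difference between the genotypes. Skeletal muscle RNA is a candidate source for KO replicate 2, which had 774 muscle miRNA reads against at most 18 in a WT library. The muscle list held 6 miRNAs, of which 5 also had at least 1 read in another library. Depletion of mature blood cells would not remove such RNA. In KO replicate 3, 12 muscle reads would bring 1.69 locus miRNA reads (at most 2.95) at the ratio of KO replicate 2, against 220 observed. If that ratio holds, muscle was not the whole source there. The ratio comes from 1 library, and its own error is not in the limit. The locus reads also differed in make-up, with 24 Mir127 and 9 Mir370 reads in KO replicate 2 and 10 and 55 in KO replicate 3. The genotype stays open as an untested explanation, with KO replicate 1 at the level of the WT libraries.

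The lower H/ACA list did not stand out from other features of the same annotated length. The 46 other features in the length range of H/ACA snoRNAs (23 miRNA, 22 snRNA and 1 miscellaneous feature) had a median log2 fold change of -0.34. The H/ACA median lay 0.057 above it (bootstrap interval -0.12 to 0.23), as length-dependent recovery would give. Of all tested snRNA features, some of them near-identical copies, 62 of 65 had lower estimates, so this match cannot separate length from RNA class. Without KO replicate 2 the H/ACA median was -0.063 (-0.18 to 0.02), and camera made no call without KO replicate 2 and WT replicate 1 (adjusted p = 0.292) or WT replicate 3 (0.0887), but called the list lower without KO replicate 2 and WT replicate 2 (0.0140, and 0.505 with an estimated correlation), so whether KO replicate 2 alone accounts for it stays open. The bootstrap treats features as independent, which they are not. No H/ACA difference beyond that of other features of this length was found, and an effect of the genotype on RNAs of this length in general was not tested and stays open.

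The share of the 45S pre-rRNA was lower in every KO library. It was not a matter of the larger share of Gm26224, because without the reads of Gm26224 the log2 ratio of the 45S share was -0.39 and the shares were 4.49% ± 0.40 in the KO and 5.88% ± 0.33 in the WT libraries. The feature's sequence includes those of the mature ribosomal RNAs, so a change in the precursor cannot be told apart from one in them. Nor can fewer reads from fragments of long RNAs in general be told apart from a change in this feature. Per mitochondrial rRNA read, the log2 ratio of the 45S pre-rRNA was -0.22, with 117.4 ± 7.3 in the KO and 136.4 ± 9.0 in the WT libraries (SD, n = 3 each). It was lower in every KO library than in every WT library (exact permutation p = 0.1, the smallest possible), but the values of KO replicate 1 and WT replicate 1 were 125.7 and 126.0, closer than the SD within either genotype. By edgeR's quasi-likelihood test the log2 fold change of the 45S pre-rRNA was -0.36 (SE 0.08, adjusted p = 0.542). The genotype stays open as an untested explanation.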
